A study of Mus musculus with 22 samples.

How the data were processed

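RNA was measured in 22 fresh-frozen mouse tumours of 3 genotypes. Tumours labelled SS18-SSX carried the fusion oncogene that defines synovial sarcoma (6 libraries), tumours labelled Smarcb1-/- lacked both copies of Smarcb1 (8 libraries, called Snf5-null below after the older name of the gene), and tumours labelled with both carried the fusion and lacked Smarcb1 (8 libraries, called combined). Smarcb1 encodes a core subunit of the SWI/SNF (BAF) chromatin remodelling complex, the complex that the SS18 part of the fusion also joins. The sample titles name the source of Cre recombinase: Myf5Cre, driven by the Myf5 gene of myogenic progenitors, or TATCre, a Cre protein that enters cells. With the Cre label this gave 6 groups: SS18-SSX with Myf5Cre (3), SS18-SSX with no Cre stated (3), Snf5-null with TATCre (5), Snf5-null with Myf5Cre (3), combined with TATCre (4) and combined with Myf5Cre (4). Libraries are named here by group and by the tag in their title. The descriptions give each library a number series, used here as a stand-in for library batch. Every Snf5-null and combined library had 1 series, the SS18-SSX Myf5Cre libraries another and the other SS18-SSX libraries another, so the series and the SS18-SSX genotype cannot be told apart. N43L and N43R of the Snf5-null TATCre group share a tag. The labels do not state that every library came from a separate animal, so the p-values measure the spread between these samples, which may in part be technical.

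Per the labels' protocols, RNA was extracted from homogenised tissue with the RNeasy Mini kit and libraries were made with the TruSeq Stranded mRNA kit, which enriches polyadenylated RNA and keeps the strand. The submitters' processing notes name cutadapt, STAR 2.7.5a, featureCounts, RSEM, DESeq2 and the mm10 genome, with no role or order given for each. The authors deposited whole-number counts per gene, not normalised, for 48440 Ensembl gene IDs in the 22 libraries. How reads that fit several genes were counted is not given in the sources used here, so genes with near-identical copies are treated as uncertain. Of the IDs, 48058 were matched to a symbol and to a position in GENCODE M21 (GRCm38, the same assembly as mm10), from which all coordinates were taken. No row without a gene name was present.

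Total counts ran from 8642648 to 25177722 per library, and the depth was lowest in SS18-SSX library A of the group with no Cre stated. On simulated counts made from the real means and library sizes, the test recovered 25.3% of genes changed by 1 log2 unit and 58.6% of those changed by 2 log2 units between combined and Snf5-null tumours (99 genes of each size among 18805). The same shares were 23.2% and 60.6% between combined and SS18-SSX tumours (99 of each among 18806), and 19.2% and 58.6% between Snf5-null and SS18-SSX tumours (99 of each among 18823). Between the Cre labels they were 6% and 39% within Snf5-null tumours (100 of each among 18811), and 8.1% and 48% within combined tumours (99 and 98 among 18792). For the interaction they were 0% of 99 and 10% of 100 genes (among 18801), and between the SS18-SSX number series 3% and 36% (100 of each among 18808). Of the simulated calls 6.7%, 4.6% and 0% were false in the 3 genotype comparisons in this order. For Cre the false share was 2.2% within Snf5-null and 3.5% within combined tumours, and it was 9.1% for the interaction and 4.9% for the number series. Far fewer genes were changed in the simulations than were called between the real genotypes (49.6% of tested genes for combined against Snf5-null tumours). The p needed for a call was thus stricter in the simulations. Their recovered and false shares do not describe the real genotype tests. In the simulations 0 of 24 unchanged gene lists were called in each comparison. Genes were simulated independently of each other, so this does not test the error for lists whose genes vary together. In the real data the estimated correlation between genes reached, for example, 0.832 for mature skeletal muscle in combined against Snf5-null tumours.

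The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 6 groups (minimum count 10, minimum total 15), which left 18929 genes holding 99.91% of the counts. Libraries were scaled by TMM, and 1 quasi-likelihood model of the 6 groups was fitted to all 22 libraries. Genotype comparisons set the mean of the 2 groups of 1 genotype against the mean of the 2 groups of another, so that each Cre group had equal weight. Cre comparisons set Myf5Cre against TATCre within a genotype, the interaction asked whether that difference depended on genotype, and the 2 SS18-SSX groups were compared to size what a number series, together with an unstated Cre, could do. A gene was called at an adjusted p (Benjamini-Hochberg) below 0.05, and every adjusted p of a single gene below comes from this edgeR test. Fold changes are given as log2 with the standard error (SE). Levels are log2 CPM (counts scaled to the TMM-adjusted library total) with a prior count of 2. They were computed here from the deposited counts and are given as mean and SD over libraries. Where a group had 0 counts of a gene in all its libraries, list medians were also computed with that group at a floor of 3 counts over the group. Floors cover counting error only.

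Gene lists were tested with camera of limma 3.58.1 (preset correlation between genes of 0.01), adjusted over the 25 lists of a comparison, and again with the correlation estimated from the data. No list in any comparison passed 0.05 with the estimated correlation. A rotation test, fry, was also run. It asks whether the genes of a list change at all, without setting them against other genes. In combined against Snf5-null tumours it passed for macrophage and myeloid genes (fry adjusted p = 3.59e-06) and not for mature skeletal muscle (0.066). Its other results are not reported here. The lists were SWI/SNF (BAF) subunits, Polycomb subunits, synovial sarcoma associated genes, Hox genes, other developmental transcription factors, early myogenic genes, mature skeletal muscle, epithelial genes, keratinocyte, neural genes, Schwann cell, fibroblast and extracellular matrix, cartilage and bone, macrophage and myeloid, T and NK cell, B cell, endothelial, adipocyte, red blood cell, interferon response, antigen presentation, cell cycle, Wnt targets, p53 targets and Cdkn2a, and hypoxia and glycolysis. Counts of called members are given over all tested genes and adjusted over the list alone.

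Genes were named by a rule. It took Smarcb1 and Ss18, then the 5 genes with the largest and the 5 with the smallest called log2 fold change in each genotype comparison, and the largest riser and faller of each list with at least 3 called members. The 5 and 5 needed a mean log2 CPM of at least 3 and every library of the higher genotype above the mean of the lower. For the Cre comparisons and the interaction the rule took 3 genes each way. Further genes named below, among them Tle1 and Ptprc and some list members, were chosen after their values were seen. Some genes that the rule selects are not reported here.

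The position of each library between the Snf5-null mean (0) and the SS18-SSX mean (1) was its projection on the axis joining them, over the genes called between those genotypes. End-genotype libraries were left out of their own mean and gene choice, and positions were compared by exact permutation. The changes of combined and of SS18-SSX tumours from Snf5-null tumours share their control libraries, so the similarity was also computed on 20 simulated sets of unchanged groups and with the Snf5-null libraries split in 35 ways. The share of each gene's 50-base stretches that occur in another gene's transcripts was computed from GENCODE M21, as a measure of reads that copies could share.

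The groups, the main tests, the gene lists, the naming rule and most alternative settings were fixed before the data were examined. The alternatives were other scalings (RLE, and library size alone, the latter added after seeing the data), no low-count filter, DESeq2 1.42.0, fits on fewer groups, genotype without Cre, N43L and N43R summed, and each library left out in turn. For the position of combined tumours only combined libraries were left out. Fits without SS18-SSX libraries N381 and A, and with N3 and N4 of the combined Myf5Cre group or N31 and N33 of the Snf5-null Myf5Cre group summed, were also added after seeing the data. No replicate pair matched within sampling noise. The closest pairs, N3 and N4 of the combined Myf5Cre group, and N43L and N43R, had chi-square values of 39.5 and 51.5 per degree of freedom. This does not show that the libraries came from separate animals. N31 and N33 had the highest correlation (0.987). The human SSX part of the fusion has no row in the table, and the transgene was not analysed here.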

Results

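The series compared the transcriptomes of mouse tumours driven by the SS18-SSX fusion, by loss of Smarcb1, or by both, to ask what each lesion contributes to the tumour. Counts were available for 6 SS18-SSX, 8 Snf5-null and 8 combined tumours, with total counts per library of 8642648 to 25177722 in SS18-SSX, 16059420 to 21807838 in Snf5-null and 14834030 to 18062578 in combined tumours. Over all tested genes the log2 CPM of 2 combined libraries correlated on average at r = 0.909, of 2 Snf5-null libraries at 0.918 and of 2 SS18-SSX libraries at 0.909. Between genotypes the mean r was 0.839 for combined with SS18-SSX, 0.817 for combined with Snf5-null and 0.785 for SS18-SSX with Snf5-null libraries (values across genes, which are not independent replicates).

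**Figure D1:**
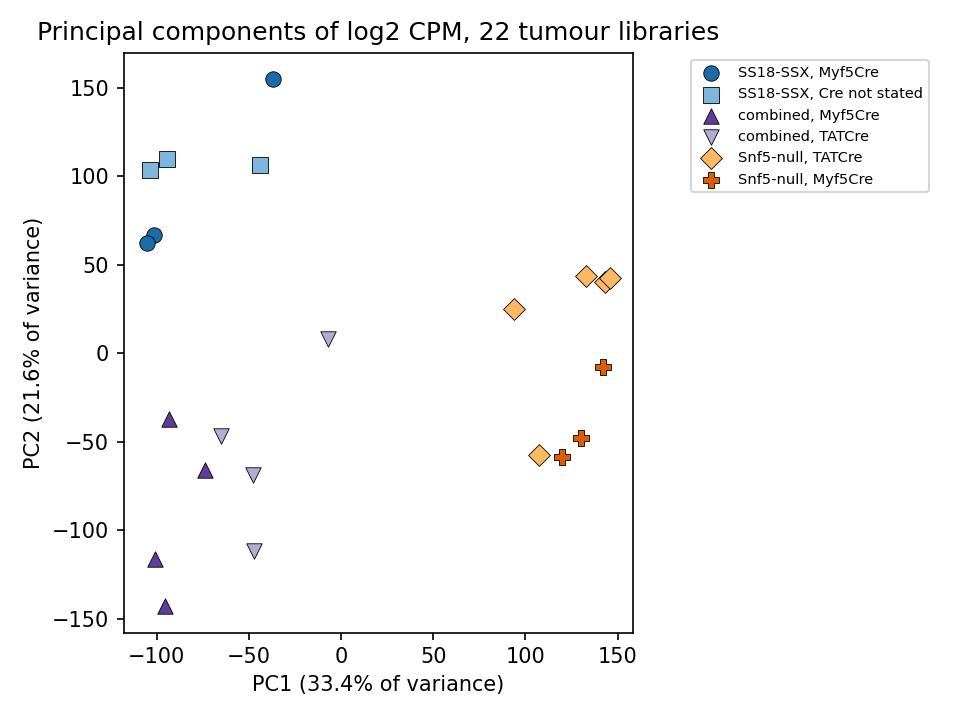
Principal components of log2 CPM, with 1 point per tumour library (n = 22), coloured and shaped by genotype and Cre label. The x axis holds PC1 (33.4% of the variance) and the y axis PC2 (21.6%); Snf5-null libraries lie to the right of the other genotypes, and SS18-SSX libraries above the combined ones.

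Smarcb1 (ENSMUSG00000000902, chromosome 10, 75896769 to 75921617, minus strand), the gene deleted in the Snf5-null and combined tumours, followed the labels in every library. It stood at 79.2 ± 23.1 CPM (SD, n = 6) in SS18-SSX tumours, with libraries between 47.1 and 111. It was at 15.9 ± 5.17 CPM (n = 8) in Snf5-null tumours, between 10.6 and 26.9, and at 2.53 ± 0.946 CPM (n = 8) in combined tumours, between 0.909 and 3.66. The remaining counts were 190 to 493 per Snf5-null library and 17 to 57 per combined library. Smarcb1 was thus lower in combined than in Snf5-null tumours, although both are labelled null (log2 fold change -2.66 ± 0.22 SE, adjusted p = 8.31e-08, 6.33-fold). The labels do not state which exons were removed, so reads from outside the deleted part cannot be set apart. Ss18 (ENSMUSG00000037013, chromosome 18, 14624198 to 14682914, minus strand), the mouse gene whose human counterpart supplies the start of the fusion, was higher in combined than in Snf5-null tumours (0.71 ± 0.16, adjusted p = 0.00161). It did not pass the test between combined and SS18-SSX tumours (0.2 ± 0.17, adjusted p = 0.36). Reads from the SS18 part of the fusion may have been counted in this row, which was not tested. These and later values of Ss18 may therefore not be of the mouse gene alone. No mouse Ssx row exceeded 1 count in any library. Tle1, a transcriptional corepressor used as a diagnostic marker of synovial sarcoma, was at 287 ± 72.1 CPM in SS18-SSX, 188 ± 22.7 in combined and 39.1 ± 7.76 in Snf5-null tumours. Ptprc, which encodes the pan-leucocyte antigen CD45, was at 272 ± 106 CPM in Snf5-null tumours against 24.4 ± 21.4 in combined and 26.6 ± 24.2 in SS18-SSX tumours.

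**Figure D2:**
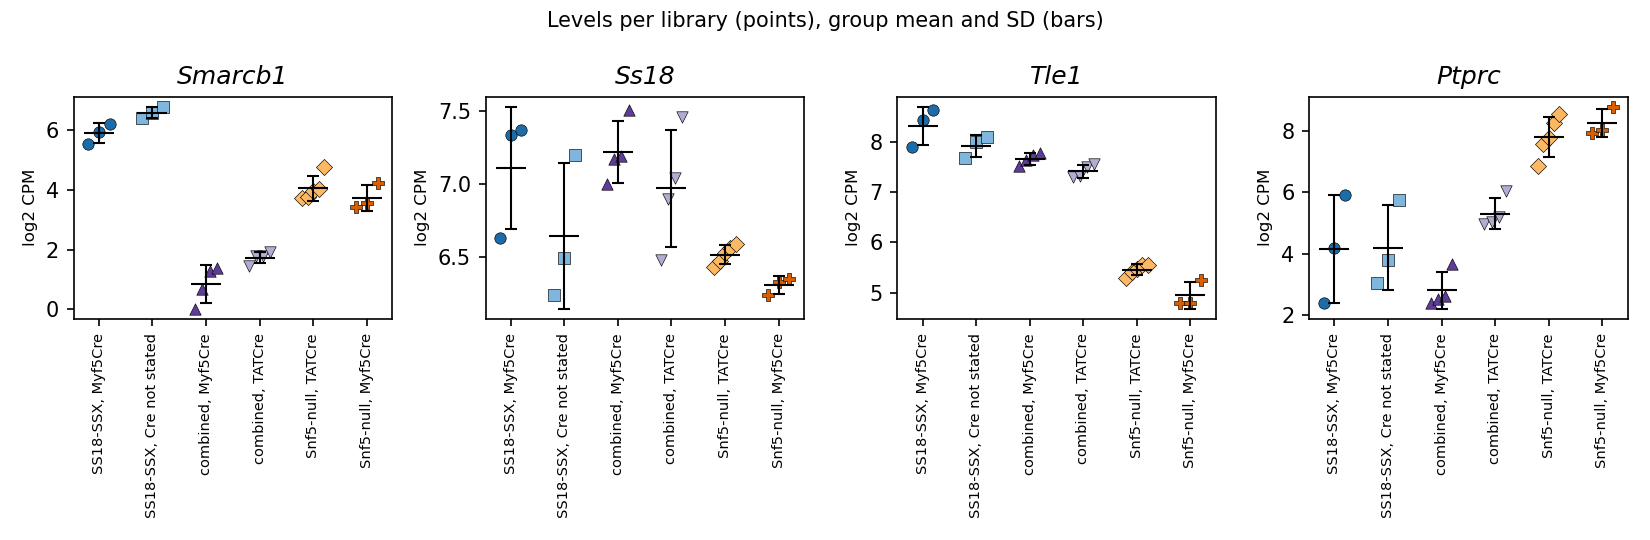
Log2 CPM of Smarcb1, Ss18, Tle1 and Ptprc (y axes, separate scales) in the 6 groups on the x axis. Points are libraries, and the horizontal and vertical bars give the group mean and SD. Smarcb1 fell into 3 ranges that did not overlap, SS18-SSX from 47.1 to 111, Snf5-null from 10.6 to 26.9 and combined from 0.909 to 3.66 CPM.

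Combined tumours were set against Snf5-null tumours to ask what SS18-SSX adds where Smarcb1 is absent. The combined tumours held more of several developmental transcripts and less of leucocyte, matrix and muscle transcripts. Sez6, a neuronal membrane protein, was higher by 7.01 ± 1.16 log2 units (adjusted p = 0.000105), at 7.5 ± 2.67 log2 CPM against 1.64 ± 1.61 (n = 8 and 8). Grin2c, an NMDA receptor subunit (6.45 ± 1.14), Tfap2c, a transcription factor of the AP-2 family (6.39 ± 1.05), Chst8, a sulfotransferase (6.66 ± 1.01), and Wfdc2 (8.48 ± 1.78) were also higher, with adjusted p values from 4.55e-05 for Chst8 to 0.000836 for Wfdc2. Ctsk, the protease cathepsin K, was lower by -7.44 ± 0.9 (2.59 ± 0.91 against 9.03 ± 2.12 log2 CPM, adjusted p = 4.04e-06). Also lower were S100a4, a calcium-binding protein (-6.74 ± 0.69), Spp1, which encodes osteopontin (-6.44 ± 0.8), Plau, the urokinase-type plasminogen activator (-6.16 ± 0.64), and Cilp, a cartilage matrix protein (-6.57 ± 1.29, adjusted p = 0.00048).

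Genes of immune cells were lower in combined than in Snf5-null tumours as groups. Of 16 macrophage and myeloid genes 0 were higher and 15 lower (0 and 15 adjusted over the list alone), with Itgam, the integrin CD11b, at -5.88 ± 0.55 (camera adjusted p = 1.6e-17, adjusted p = 0.193 with an estimated correlation). Of 21 T and NK cell genes 17 were lower (18 adjusted over the list alone, camera adjusted p = 4.75e-06, adjusted p = 0.404 with an estimated correlation). The median log2 fold change was -3.96, or -3.67 with groups at 0 counts set to the floor. Of 10 B cell genes 9 were lower (9 adjusted over the list alone), among them the immunoglobulin light chain Igkc at -6.94 ± 1.51 (camera adjusted p = 0.00153, adjusted p = 0.442 with an estimated correlation). Of 24 interferon response genes 18 were lower and 0 higher (18 and 0 adjusted over the list alone), led by Ifit3 at -4.34 ± 0.68 (camera adjusted p = 5.18e-08, adjusted p = 0.404 with an estimated correlation). Of 16 antigen presentation genes 13 were lower (13 adjusted over the list alone), with Cd74, the MHC class II invariant chain, at -4.8 ± 0.85 (camera adjusted p = 8.11e-05, adjusted p = 0.404 with an estimated correlation).

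Matrix and muscle genes were also lower in combined than in Snf5-null tumours. Of 23 fibroblast and extracellular matrix genes 13 were lower and 0 higher (13 and 0 adjusted over the list alone), led by the microfibril protein Mfap5 at -5.06 ± 1.03 (camera adjusted p = 0.000261, adjusted p = 0.442 with an estimated correlation). Of 22 mature skeletal muscle genes 16 were lower and 0 higher (16 and 0 adjusted over the list alone, camera adjusted p = 0.00652, adjusted p = 0.659 with an estimated correlation). These genes varied widely, with a list mean of 5.83 ± 2.41 log2 CPM in Snf5-null and 3.02 ± 1.55 in combined tumours. The largest faller of the list, the calcium-binding protein Pvalb, was lower by -5.21 ± 1.5 and lost the call without Snf5-null Myf5Cre library N30 (-2.98, adjusted p = 0.0895). All 5 red blood cell genes were higher in combined tumours (5 adjusted over the list alone), with the beta-globin Hbb-bt at 3.9 ± 0.85 (camera adjusted p = 0.0489, adjusted p = 0.53 with an estimated correlation), and globin copies can share reads. Of 15 endothelial genes 3 were higher (Egfl7, Flt1, Cldn5) and 4 lower (Sox18, Tek, Pecam1, Erg), with the same counts adjusted over the list alone (camera adjusted p = 0.614, 0.865 with an estimated correlation). Of 9 adipocyte genes the lipase Lpl alone was lower, at -1.31 (1 adjusted over the list alone, camera adjusted p = 0.408). The list's median of 0 and mean of 0.2 differed in sign from the camera direction, which was down.

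Developmental genes went the other way. Of 52 other developmental transcription factors 31 were higher and 2 lower, En1 and Gata6 (31 and 3 adjusted over the list alone), with the paired-box factor Pax6 at 6.96 ± 1.17 (camera adjusted p = 0.000417, adjusted p = 0.404 with an estimated correlation). Of 22 synovial sarcoma associated genes 14 were higher and 3 lower, Bcl2, Crabp1 and Sox9 (14 and 3 adjusted over the list alone, camera adjusted p = 9.46e-05, adjusted p = 0.193 with an estimated correlation). The Wnt receptor gene Fzd10 was at 5.67 ± 0.93 and the retinoic acid binding protein gene Crabp1 at -4.33 ± 0.99. Of 37 Hox genes 18 were higher and 1, Hoxd13, lower (the same counts adjusted over the list alone), which did not pass the list test (camera adjusted p = 0.11, or 0.0439 with RLE scaling). The Hox list mean was lower in Snf5-null than in combined tumours with Myf5Cre (-1.66 ± 0.13 against -0.11 ± 0.78 log2 CPM, n = 3 and 4) and near it with TATCre (1.17 ± 0.71 against 1.1 ± 0.91, n = 5 and 4). Of 26 Polycomb subunits 16 were higher and 2 lower, Ezh1 and Pcgf5 (17 and 2 adjusted over the list alone, camera adjusted p = 0.02, adjusted p = 0.404 with an estimated correlation). Cbx2 was at 2.63 ± 0.3 and Pcgf5 at -3.05 ± 0.25. Of 29 SWI/SNF (BAF) subunits 12 were higher, led by Bcl11b at 3.25 ± 0.67, and 2 lower, Smarcd3 and Smarcb1 itself (the same counts adjusted over the list alone, camera adjusted p = 0.283). Of 14 Wnt targets 5 were higher (Sp5, Lef1, Nkd1, Axin2, Apcdd1) and 4 lower (Wif1, Rnf43, Myc, Dkk1), with the same counts adjusted over the list alone (camera adjusted p = 0.0489, adjusted p = 0.404 with an estimated correlation).

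Of 25 cell cycle genes 11 were higher in combined than in Snf5-null tumours and 0 lower (11 and 0 adjusted over the list alone, camera adjusted p = 0.00813, adjusted p = 0.659 with an estimated correlation). Epithelial genes (11 higher, 2 lower, Cldn4 and Krt7, of 21) and neural genes (12 higher, 3 lower, Map2, Snap25 and Nefl, of 22) did not pass the list test (camera adjusted p = 0.312 and 0.163). Adjusted over the list alone these counts were 11 and 2, and 13 and 3. Of 22 early myogenic genes 4 were higher, among them Eya1, Msc and Pax7, and 6 lower (the same adjusted over the list alone, camera adjusted p = 0.357), with the phosphatase Eya1 at 4.85 ± 0.74. Of 12 cartilage and bone genes 3 were higher and 5 lower (the same adjusted over the list alone, camera adjusted p = 0.203), with the collagen Col2a1 at 6.09 ± 1.2. Schwann cell genes (2 higher, among them Erbb3, and 3 lower, Mag, S100b and Mbp, of 10) and keratinocyte genes (2 higher, Lor and Krt15, and 2 lower, Lgals7 and Col17a1, of 11) gave camera adjusted p values of 0.163 and 0.821, with the same counts adjusted over the list alone. Without combined TATCre library 78777 the fold change of Erbb3 moved from 2.97 to 1.98, and without 78774 that of Col17a1 moved from -2.62 to -4.51. Of 17 p53 targets and Cdkn2a 1, Perp, was higher and 6 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.16), led by Eda2r, a member of the TNF receptor family, at -2.48 ± 0.49. Of 16 hypoxia and glycolysis genes 7 were higher and 2 lower, Hk2 and Pfkfb4 (the same adjusted over the list alone, camera adjusted p = 0.303), with the vasodilator peptide gene Adm at 2.85 ± 0.5. Perp (2.02, adjusted p = 0.0496) lost its call with RLE scaling (1.88, adjusted p = 0.0674). It also lost it without combined Myf5Cre library N1 (1.58), N2 (1.94) or N4 (1.97), or combined TATCre library 78777 (0.71). The same held without Snf5-null Myf5Cre library N30 (1.68), N31 (1.91) or N33 (2.02), or Snf5-null TATCre library N1 (1.92), N43L (2.03) or N51 (1.98). Cldn4 (-3.12, adjusted p = 0.0449) dropped to -0.5 (adjusted p = 0.693) without Snf5-null TATCre library N1. Its call was also lost without Snf5-null Myf5Cre library N30 (-2.88) or N31 (-3.28), combined Myf5Cre library N2 (-3.02), N3 (-2.93) or N4 (-3.17), or combined TATCre library N49 (-2.89), 78774 (-2.92) or 78780 (-3.2).

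In all, 5509 genes were higher and 3874 lower in combined than in Snf5-null tumours at an adjusted p below 0.05 in edgeR, of which 3116 and 3125 differed by at least 1 log2 unit. The number of genes higher was 3134 without Snf5-null Myf5Cre library N30, 3262 without N31 and 3592 without N33. The median log2 fold change over all genes, 0.235 in the main fit, was 0.113, 0.101 and 0.102 in these fits. It was 0.093 with N31 and N33 summed, which removes no reads, and 0.072 and 0.092 without combined Myf5Cre library N1 or N4. A shift of all genes with the scaling and a dependence on single tumours were not told apart. The share of higher calls was 58.7%, against 51.2% with RLE scaling (median shift -0.115) and 46.1% without the low-count filter. It was also under 50% without Snf5-null Myf5Cre library N30 (45.2%), N31 (44.7%) or N33 (45.8%), without combined Myf5Cre library N1 (49%) or N4 (47.8%), with genotype alone (48.8%), with Myf5Cre (42%) or TATCre libraries (40.7%) alone, and with N31 and N33 summed (44.9%).

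**Figure D3:**
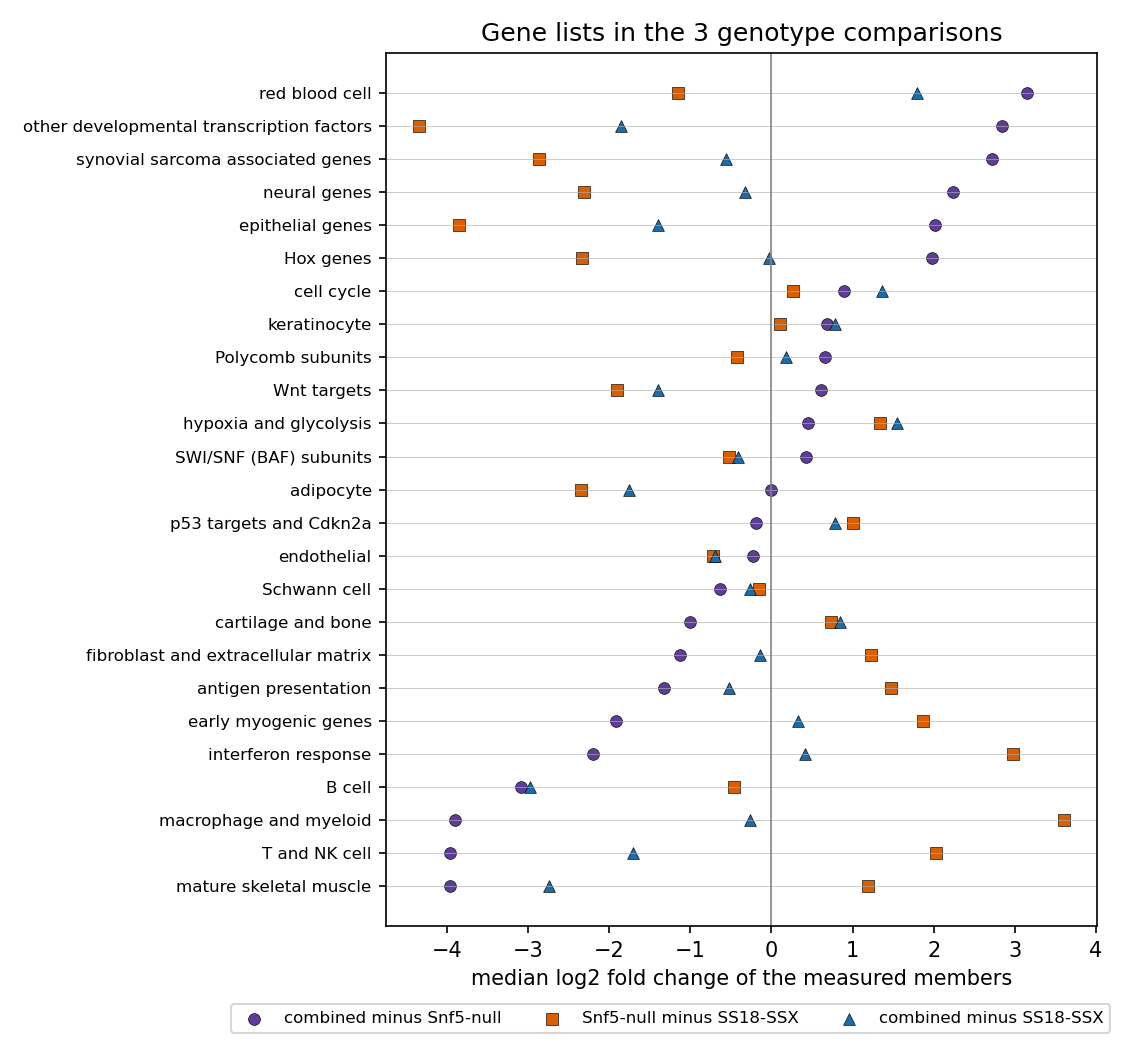
Median log2 fold change over the measured members of each of the 25 gene lists (x axis) in the 3 genotype comparisons (colours and symbols), with lists on the y axis ordered by combined minus Snf5-null. Macrophage and myeloid genes lay at -3.9 in combined minus Snf5-null and at 3.61 in Snf5-null minus SS18-SSX; with groups at 0 counts set to the floor, T and NK cell genes moved from -1.71 to -1.03 in combined minus SS18-SSX and from -3.96 to -3.67 in combined minus Snf5-null.

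Combined tumours were set against SS18-SSX tumours to ask what loss of Smarcb1 changes in the presence of the fusion. Besides Smarcb1 itself (-4.99 ± 0.25, adjusted p = 5.24e-10, n = 8 and 6), combined tumours held less of Tmtc1, a membrane mannosyltransferase (-5.09 ± 0.67, 0.97 ± 0.89 against 6.16 ± 0.46 log2 CPM), Wif1, a secreted Wnt inhibitor (-5.08 ± 1.06), Col4a6, a basement membrane collagen (-4.88 ± 0.85), and Map2, a neuronal microtubule-associated protein (-4.6 ± 0.82). They held more of Mgarp, a mitochondrial protein (5.26 ± 0.88, 5.36 ± 1.16 against -0.53 ± 2.07 log2 CPM), and the interferon-induced Ifi27l2a (3.97 ± 0.93). Adjusted p values of these genes ran from 3.02e-05 for Tmtc1 to 0.00238 for Ifi27l2a. The ribozyme gene Rprl3, a noncoding RNA that poly(A) selection should largely leave out, was at 4.5 ± 0.48, and its level in SS18-SSX tumours differed between groups, at 4.39 log2 CPM with Myf5Cre and -0.46 with no Cre stated. Wfdc2 (4.31 ± 1.48) lost its call without combined TATCre library 78777 (1.86, adjusted p = 0.164) and also without SS18-SSX library N428 (4.09, 0.0559), B (4.1, 0.0611) or N2 (4.04, 0.0586).

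Cell cycle and hypoxia genes were higher as lists in combined than in SS18-SSX tumours. Of 25 cell cycle genes 17 were higher and 0 lower (18 and 0 adjusted over the list alone), led by the kinase Cdk1 at 2.44 ± 0.47 (camera adjusted p = 3.05e-05, adjusted p = 0.909 with an estimated correlation). Of 16 hypoxia and glycolysis genes 11 were higher and 0 lower (12 and 0 adjusted over the list alone), led by the glycolytic enzyme Pgk1 at 3.62 ± 0.33 (camera adjusted p = 4.99e-06, adjusted p = 0.867 with an estimated correlation). Transcripts of some of these genes have copies elsewhere in the genome, as 45.5% of the 50-base stretches of Pgk1 and 23.9% of those of Eno1 occur in other genes. Among list members sharing under 5% of their stretches, a limit chosen after seeing the data, 12 of 19 cell cycle and 7 of 12 hypoxia and glycolysis genes were higher and 0 lower. Of 52 other developmental transcription factors 18 were lower and 4 higher, among them Lhx3, Barx1 and Six2 (the same adjusted over the list alone), with the homeobox gene En2 at -6.07 ± 0.86 (camera adjusted p = 0.009, adjusted p = 0.909 with an estimated correlation). Of 21 epithelial genes 7 were lower and 0 higher (3 and 0 adjusted over the list alone, camera adjusted p = 0.0368, adjusted p = 0.909 with an estimated correlation), with the keratin Krt18 at -3.88 ± 0.97, or -6.96 without combined TATCre library 78777.

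Other groups gave no list call between combined and SS18-SSX tumours. Of 16 macrophage and myeloid genes 0 were called at either sign over all genes or adjusted over the list alone (camera adjusted p = 0.774), with list means of 3.52 ± 1.03 and 3.61 ± 1.06 log2 CPM. Of 14 Wnt targets 9 were lower and 1, Myc, higher by 2.05 ± 0.31 (the same adjusted over the list alone, camera adjusted p = 0.0645). Of 29 SWI/SNF subunits 11 were lower and 5 higher, Actl6a, Bcl7c, Brd7, Smarce1 and Smarcd2 (the same adjusted over the list alone, camera adjusted p = 0.0645). The 11 include Smarcb1, deleted by design. Of 22 synovial sarcoma associated genes 8 were lower and 3 higher, Igf2, Meox2 and Sox8 (the same adjusted over the list alone, camera adjusted p = 0.0721). The homeobox gene Meox2 moved from 4.55 ± 1.13 to 2.33 without combined TATCre library 78774. Of 10 B cell genes 9 were lower (10 adjusted over the list alone, camera adjusted p = 0.0645). Of 22 mature skeletal muscle genes 4, Casq1, Ryr1, Tcap and Pygm, were lower (0 adjusted over the list alone, camera adjusted p = 0.561). SS18-SSX libraries N381 and A stood apart in both groups, with muscle list means of 7.14 and 7.82 log2 CPM against -0.99 to 3.18 in the other SS18-SSX libraries. Their B cell list means were 2.45 and 4.18, against -1.74 to -0.66. Igkc moved from -8.23 ± 1.59 to -4.08 without N381 and -5.4 without A, and the muscle calcium-binding protein Casq1 from -3.42 to -1 (adjusted p = 0.536) and -1.6 (0.298). Casq1 also lost its call without combined Myf5Cre library N3 or N4 (-3.3 and -3.26) or TATCre library 78774, 78777 or 78780 (-3.31, -3.35 and -3.18). For the cartilage and bone list the median (0.85) differed in sign from the mean (-0.37) and from the camera direction.

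In all, 4372 genes were higher and 4146 lower in combined than in SS18-SSX tumours in edgeR, or 51.3% higher, against 37.6% (3300 and 5483) when libraries were scaled by library size alone, which shifted the median by -0.214. It was 46.6% with RLE scaling, 47% with DESeq2, 42.5% without the low-count filter and 40% with Myf5Cre libraries alone, and 50.9% to 54.6% with 1 library left out. Every combined library had another number series than every SS18-SSX library, so a library batch and the genotype cannot be told apart in this comparison.

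Snf5-null tumours were set against SS18-SSX tumours to compare the single lesions. Snf5-null tumours held more of S100a4 (8.29 ± 0.85, 9.34 ± 1.02 against 1.21 ± 0.89 log2 CPM, n = 8 and 6, adjusted p = 1.38e-06), Vgll3, a cofactor of TEAD transcription factors (7.39 ± 1.29), Ifi27l2a (7.38 ± 1.1), Ptgis, the prostacyclin synthase (6.99 ± 0.98), and Medag (6.61 ± 0.99). They held less of Sez6 (-9.58 ± 1.32, 1.64 ± 1.61 against 10.43 ± 2.01 log2 CPM, adjusted p = 1.82e-05), the zinc finger factor Zic2 (-8.81 ± 1.13), the cadherin Cdh4 (-8.44 ± 0.88), Sez6l (-8 ± 0.7) and Col2a1 (-7.78 ± 1.33). Smarcb1 was lower by -2.33 ± 0.23 (adjusted p = 9.56e-07). Ss18 was lower by -0.52 ± 0.17 (adjusted p = 0.0187), a call lost without Snf5-null Myf5Cre library N30 (-0.38), N31 (-0.38) or N33 (-0.35), or SS18-SSX library N428 (-0.31), N460 (-0.31), B (-0.42) or N2 (-0.2).

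Macrophage, interferon, T and NK cell and antigen presentation genes were higher as lists in Snf5-null than in SS18-SSX tumours, while of 10 B cell genes 0 were called over all genes or adjusted over the list alone. The B cell list means of SS18-SSX libraries N381 (2.45) and A (4.18) lay above the Snf5-null range of 0.38 to 2.22 log2 CPM, and those of the other 4 SS18-SSX libraries below it (-1.74 to -0.66). Of 16 macrophage and myeloid genes 15 were higher and 0 lower (the same adjusted over the list alone), with Itgam at 5.61 ± 0.62 (camera adjusted p = 9.18e-14, adjusted p = 0.144 with an estimated correlation). Of 24 interferon response genes 21 were higher and 0 lower (23 and 0 adjusted over the list alone), with the chemokine Cxcl10 at 4.95 ± 1.16 (camera adjusted p = 1.4e-11, adjusted p = 0.182 with an estimated correlation). Of 21 T and NK cell genes 8, and of 16 antigen presentation genes 10, were higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.000774 for each, adjusted p = 0.452 and 0.43 with an estimated correlation). H2-Aa, an MHC class II chain, was at 2.75 ± 0.9, or 4.56 without SS18-SSX library N381. Of 23 fibroblast and extracellular matrix genes 9 were higher and 0 lower (the same adjusted over the list alone), with the collagen cross-linking enzyme Lox at 4.51 ± 0.85 (camera adjusted p = 0.00388, adjusted p = 0.528 with an estimated correlation). Of 17 p53 targets and Cdkn2a 10 were higher and 1, Perp, lower (the same adjusted over the list alone, camera adjusted p = 0.00091, adjusted p = 0.182 with an estimated correlation). Of 16 hypoxia and glycolysis genes 10 were higher and 1, Vegfa, lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.000774, adjusted p = 0.353 with an estimated correlation). Perp (-2.58) lost its call without Snf5-null Myf5Cre library N30 (-2.24) or N31 (-2.47), or SS18-SSX library N381 (-2.26), N460 (-2.25) or A (-2.04). Among the hypoxia members sharing under 5% of their stretches 6 of 12 were higher and 1 lower.

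Developmental and synovial sarcoma associated genes were lower in Snf5-null than in SS18-SSX tumours. Of 52 other developmental transcription factors 38 were lower and 1 higher (41 and 2 adjusted over the list alone, camera adjusted p = 1.11e-08, adjusted p = 0.144 with an estimated correlation). Of 22 synovial sarcoma associated genes 15 were lower and 2 higher, Crabp1 and Meox2 (16 and 2 adjusted over the list alone), with Fzd10 at -7.53 ± 1.02 (camera adjusted p = 1.37e-07, adjusted p = 0.0501 with an estimated correlation). Of 14 Wnt targets 9 were lower and 1, Myc, higher by 2.79 ± 0.32 (10 and 2 adjusted over the list alone, camera adjusted p = 0.000276, adjusted p = 0.0501 with an estimated correlation). Of 29 SWI/SNF subunits 14 were lower, led by Bcl11b at -4.84 ± 0.74, and 1, Actl6a, higher (the same adjusted over the list alone, camera adjusted p = 0.00214, adjusted p = 0.261 with an estimated correlation). The 14 include Smarcb1, deleted by design, and Ss18. Of 26 Polycomb subunits 12 were lower and 5 higher, Bmi1, Rbbp7, Rbbp4, Eed and Pcgf5 (the same adjusted over the list alone, camera adjusted p = 0.0446, adjusted p = 0.422 with an estimated correlation). The corepressor gene Bcor was at -3.83 ± 0.29 and Pcgf5 at 3.2 ± 0.28, and Bmi1 shares 15.5% of its stretches with other genes. Epithelial genes (13 lower and 2 higher, Cldn4 and Krt7, of 21, camera adjusted p = 0.00214), Hox genes (11 lower of 37, camera adjusted p = 0.0188) and neural genes (12 lower and 3 higher, Snap25, Nes and Nefl, of 22, camera adjusted p = 0.0302) were lower as lists. The Hox list mean was 1.17 ± 0.71 log2 CPM in Snf5-null TATCre (n = 5), -1.66 ± 0.13 in Snf5-null Myf5Cre (n = 3) and 0.9 ± 1.23 in SS18-SSX tumours (n = 6). Members differed, and Hoxd12, the largest faller, was at -2.84 with TATCre and -3.12 with Myf5Cre against 0.39 log2 CPM in SS18-SSX tumours. The Hox list did not pass when scaled by library size alone (camera adjusted p = 0.0823). Adjusted over the list alone the counts of epithelial, Hox and neural genes were 14 and 2, 10 and 0, and 12 and 3, and with an estimated correlation the adjusted p values were 0.528, 0.623 and 0.395. Cldn4 (3.82 ± 1.45) dropped to 1.22 (adjusted p = 0.353) without Snf5-null TATCre library N1 and also lost its call without Snf5-null Myf5Cre library N30 (3.59) or SS18-SSX library N428 (3.7), N460 (3.79), A (3.76) or N2 (3.93). The myogenic regulator Myf5 was higher by 9.59 ± 2.6, its levels spreading from -1.58 to 8.08 log2 CPM among Snf5-null libraries.

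In all, 4217 genes were higher and 4910 lower in Snf5-null than in SS18-SSX tumours in edgeR, or 46.2% higher, against 33.2% (3142 and 6333) when scaled by library size alone, which shifted the median by -0.241. The balance turned when any SS18-SSX library was left out, at 55.7% higher without N381, 55% without N428, 54.8% without N460, 54.9% without A, 53.9% without B and 55.2% without N2. It also turned without Snf5-null Myf5Cre library N30 (54.8%), N31 (55.4%) or N33 (55.4%), with genotype alone (55.9%) and with N31 and N33 summed (55.7%). For 2 lists without a camera call the measures differed in sign: B cell genes had a median of -0.46 and a mean of -0.23 with an upward test (camera adjusted p = 0.369), and Schwann cell genes a median of -0.15 and a mean of 0.18. The number series again differed fully between these genotypes.

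On the axis from Snf5-null (0) to SS18-SSX tumours (1) over 9331 genes, combined tumours lay at 0.58 ± 0.089 (SD, n = 8), with libraries between 0.454 and 0.735. Snf5-null libraries, each left out of its own mean, lay at 0.033 ± 0.095 (n = 8) and SS18-SSX libraries at 0.94 ± 0.097 (n = 6). Combined tumours differed from Snf5-null tumours of the same number series (two-sided exact permutation p = 0.000155 over 12870 splits, the smallest they can give). They also differed from SS18-SSX tumours (two-sided exact permutation p = 0.000333, the smallest that design can give), where the number series differed. The position was 0.628 ± 0.078 (n = 4) with Myf5Cre and 0.532 ± 0.078 (n = 4) with TATCre. A tumour type unlike both ends would also lie between them, since it would lack what is particular to Snf5-null tumours. The position and its p-values thus do not show a move towards SS18-SSX tumours.

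**Figure D4:**
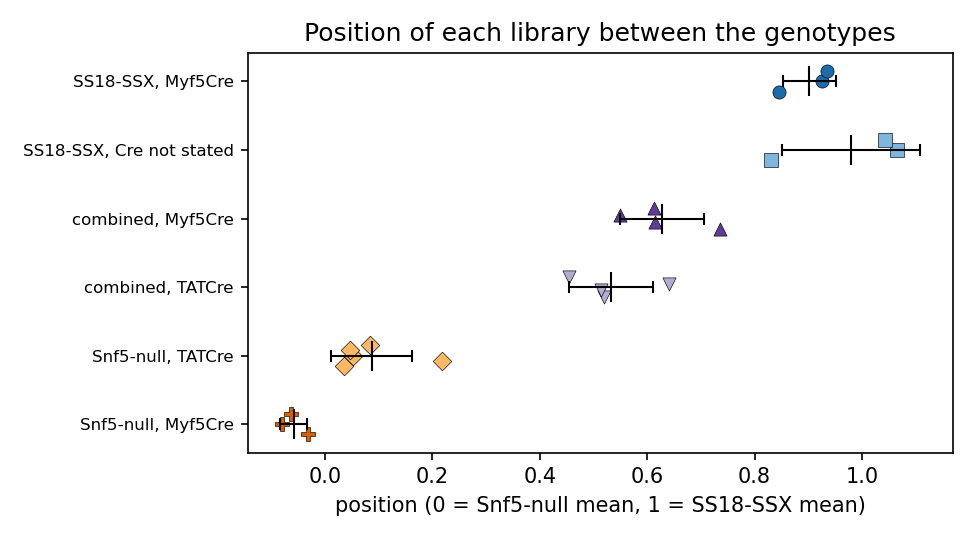
Position of each library (points) on the axis from the Snf5-null mean (0) to the SS18-SSX mean (1), with groups on the y axis and bars for group mean and SD. Along this axis combined libraries lay between 0.454 and 0.735, between the libraries of the other genotypes. Distance off the axis is not shown.

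The change from Snf5-null to combined tumours was also compared with the change from Snf5-null to SS18-SSX tumours. Of the called genes, 2506 were higher in both and 2169 lower in both, while 504 genes were higher in combined and lower in SS18-SSX tumours and 114 the reverse. Both changes share the Snf5-null control libraries. These were therefore split into separate controls, a test chosen after seeing the data (15 splits that kept N43L and N43R together, each used both ways). On average 3078 genes were called the same way (3018 to 3248) and 386 in opposite ways (84 to 1622). The former were more in 30 of 30 fits, which reuse the same libraries. Separate controls remove shared sampling noise only. A gene particular to Snf5-null tumours would still be called the same way in both changes. Neither these counts nor the correlations below therefore show a shared effect of the fusion. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.672 with a covariance of 1.725, against r = 0.461 and a covariance of 0.111 for unchanged groups against the same controls. The difference in covariance was 1.614, and with the Snf5-null libraries split into separate controls r averaged 0.607, from 0.461 to 0.645 over 35 splits, with a covariance of 1.616. The share of genes with the same sign was 65.2%, against 65.3% for unchanged groups with shared controls, and 63.7% with separate controls.

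Within Snf5-null tumours, Myf5Cre was set against TATCre. TATCre library N1 correlated with the other TATCre libraries at r = 0.882 to 0.892, against 0.951 to 0.982 among those. On PC2 it lay at -57.6, near Myf5Cre libraries N31 (-48) and N33 (-58.6), while the other TATCre libraries lay at 25 to 43.8. Peg3, a paternally expressed imprinted gene, was higher with Myf5Cre by 5.11 ± 0.49 (11.5 against 6.3 log2 CPM, n = 3 and 5, edgeR adjusted p = 2.29e-05), as were Rtl1, an imprinted retrotransposon-derived gene (5.19 ± 0.93), and the growth factor gene Bmp3 (5.77 ± 1.17). Stmn2, a neuronal microtubule regulator, was lower by -8.08 ± 1.38, and Ism1 by -8.2 ± 2.19. Of 37 Hox genes 13 were lower and 1, Hoxd13, higher (23 and 1 adjusted over the list alone, camera adjusted p = 4.62e-13, adjusted p = 0.321 with an estimated correlation). The lower ones included Hoxa2 to Hoxa5, Hoxa7, Hoxa9 to Hoxa11, Hoxc11, Hoxc13, Hoxd8 and Hoxd9, with log2 fold changes from -4.2 ± 1.16 for Hoxd8 to -10.21 ± 2.64 for Hoxa11 and a median of -5.76 that the floor left at -5.76. Over all 37 the median was -4.93, or -4.27 with the floor. The processed pseudogene Rps3a3 was lower by -8.45 ± 0.88, but 64.4% of its 50-base stretches occur in other genes, so its reads may belong to a copy. Other lists passed the test at the preset correlation with few called genes. Of 22 synovial sarcoma associated genes 2, Lef1 and Pdgfra, were lower (8 adjusted over the list alone, median -1.41, camera adjusted p = 0.000158, adjusted p = 0.321 with an estimated correlation). Of 23 fibroblast and extracellular matrix genes 1, Pdgfrb, was lower (1 adjusted over the list alone, median -1.29, camera adjusted p = 0.00149, adjusted p = 0.724 with an estimated correlation). Of 15 endothelial genes 2 were lower, Sox18 and Erg (2 adjusted over the list alone, median -0.68, camera adjusted p = 0.0174, adjusted p = 0.744 with an estimated correlation). Of 22 mature skeletal muscle and 9 adipocyte genes 0 were called over all genes or adjusted over the list alone (medians -1.61 and -4.11, the latter -3.34 with the floor, camera adjusted p = 0.0365 and 0.0404, adjusted p = 0.85 and 0.744 with an estimated correlation). Upward, 1 gene each was called of 25 cell cycle genes (Foxm1), 24 interferon response genes (Rsad2) and 17 p53 targets and Cdkn2a (Zmat3), with the same counts adjusted over the list alone, medians of 1.18, 0.88 and 0.52, camera adjusted p values of 1.08e-08, 0.000159 and 0.0404, and an adjusted p of 0.724 for each with an estimated correlation. Of 14 Wnt targets 1, Lef1, was lower and 1, Notum, higher (6 and 2 adjusted over the list alone, median -1.44, camera adjusted p = 0.0404, adjusted p = 0.54 with an estimated correlation). The calls of these list members were not repeated with 1 library left out. In all 337 genes were higher and 603 lower (35.9% higher, but 54.1% without Myf5Cre library N31, 59.4% without N33 and 59.7% with these summed). The total of 940 was 559 with N43L and N43R summed, 124 with N31 and N33 summed, 1959 without TATCre library N1, 598 without N49, 521 without N43L and 523 without N43R, and 558 without Myf5Cre library N30, 122 without N31 and 138 without N33. Ism1 lost its call without Myf5Cre library N30 (-9.65), N31 (-7.66) or N33 (-7.94), or TATCre library N43L (-8.19), N43R (-8.13) or N49 (-7.92).

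Within combined tumours, Myf5Cre was again set against TATCre. F2rl1, a protease-activated receptor, was higher with Myf5Cre by 6.19 ± 0.83 (6.06 against -0.04 log2 CPM, n = 4 and 4, edgeR adjusted p = 0.00184), as were Capn6, a calpain (5.7 ± 0.84), and Smoc2, a matricellular protein (5.26 ± 1.01). Tm4sf1, a tetraspanin-like membrane protein, was lower by -5.17 ± 0.88 and Nol3, an inhibitor of apoptosis, by -5.07 ± 1. Nol3 lost its call without Myf5Cre library N3 (-5.06, adjusted p = 0.0642) or N4 (-4.78, 0.0724). Rps3a3, with shared reads as above, was lower by -6.96 ± 0.71. Of 16 macrophage and myeloid genes 1, Adgre1, was lower (13 adjusted over the list alone, camera adjusted p = 1.76e-09, adjusted p = 0.656 with an estimated correlation). Of 21 T and NK cell genes 0 were called (9 lower adjusted over the list alone, camera adjusted p = 4.06e-06, adjusted p = 0.656 with an estimated correlation). Of 37 Hox genes 0 were called over all genes or adjusted over the list alone (camera adjusted p = 0.00861 downwards, adjusted p = 0.656 with an estimated correlation). Of 24 interferon response genes 2, Gbp2 and Gbp3, were lower (6 adjusted over the list alone, camera adjusted p = 6.9e-06), and of 17 p53 targets and Cdkn2a 2, Cdkn2a and Cdkn2b (3 adjusted over the list alone, camera adjusted p = 0.047). Antigen presentation (camera adjusted p = 8.33e-05), mature skeletal muscle (0.00654), B cell (0.00654) and endothelial genes (0.0446) were lower and red blood cell genes (0.0353) higher as lists with 0 called genes (1 B cell and 1 endothelial gene lower adjusted over the list alone). With an estimated correlation the adjusted p values of these 7 lists were 0.656 to 0.702. In all 108 genes were higher and 236 lower (31.4% higher, against 46.9%, or 106 and 120, when scaled by library size alone, with a median shift of 0.107). Higher calls were the majority without Myf5Cre library N2 (57 and 54), N3 (45 and 36) or N4 (34 and 21, 61.8%), and when only combined tumours were fitted (17 and 6, 73.9%) or N3 and N4 were summed (45 and 29). The total of 344 was 74 with N3 and N4 summed, 164 without TATCre library N49, 540 without 78774 and 611 without 78777, and 159, 111, 81 and 55 without Myf5Cre libraries N1, N2, N3 and N4.

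The interaction test asked for which genes the Cre difference depended on genotype. It called 249 genes with a larger Myf5Cre minus TATCre difference in combined than in Snf5-null tumours and 209 with a smaller one (edgeR). The share of the larger class was 54.4%, against 48.3% without Snf5-null Myf5Cre library N31, 40% without N33, 48.5% without combined TATCre library 78780 and 47% without SS18-SSX tumours in the fit. With N31 and N33 summed it was 43%. Of 37 Hox genes 5 were in the larger class, among them Hoxa2, Hoxa5, Hoxa7 and Hoxa10, and 1, Hoxd13, in the smaller (12 and 1 adjusted over the list alone, camera adjusted p = 2.34e-05, adjusted p = 0.599 with an estimated correlation). Of 24 interferon response genes 3, Gbp2, Gbp3 and Cxcl10, were in the smaller class and 0 in the larger (5 and 0 adjusted over the list alone, camera adjusted p = 7.15e-10, adjusted p = 0.5 with an estimated correlation). Other lists in the smaller class by the camera test were macrophage and myeloid (camera adjusted p = 2.34e-05), T and NK cell (3.22e-05), cell cycle (0.000189), antigen presentation (0.00148), p53 targets and Cdkn2a (0.00159) and B cell (0.0483), with 3 called genes in all, Gzma, Cdkn2a and Cdkn2b. Adjusted over the list alone 6 T and NK cell genes and 4 of the p53 list were called there and 0 of the other 4 lists. In the larger class were synovial sarcoma associated genes (0.000189, with Pdgfra called), red blood cell (0.00496) and adipocyte genes (0.0168). Adjusted over the list alone 7 of 9 adipocyte genes were called higher, 2 synovial sarcoma associated genes higher and 1 lower, and 0 red blood cell genes. The adipocyte list mean spread widely among combined Myf5Cre libraries, from -1.59 to 4.57 log2 CPM (0.43 ± 2.81, SD, n = 4). With TATCre it ran from -1.1 to 0.46 in combined tumours (n = 4). The adipocyte result may thus rest on 1 library, which was not tested. With an estimated correlation the adjusted p values of these 9 lists were 0.5 to 0.697. The total of 458 was 1053 without Snf5-null TATCre library N1, 244 without N43L and 275 without N43R, 302 without Snf5-null Myf5Cre library N30, 60 without N31 and 90 without N33. It was 700 without combined TATCre library 78774 and 251, 254 and 223 without combined Myf5Cre libraries N2, N3 and N4.

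The SS18-SSX groups, which differ in number series and in whether a Cre is stated, differed in 400 genes in edgeR, 236 of them higher with Myf5Cre and 164 lower (n = 3 and 3). With SS18-SSX libraries alone in the fit edgeR called 1 gene, Rprl2, higher and 0 lower. DESeq2 called 762 and 588 genes on all libraries, and 63 and 52 were called without the low-count filter. The total was 602 without library N381, 68 without N428, 107 without N460, 83 without A, 33 without B and 792 without N2. The higher genes were the fewer without N460 (52 and 55) or A (38 and 45). Antigen presentation (median -0.92, camera adjusted p = 0.00554), mature skeletal muscle (-1.27, 0.0118), red blood cell (-2.79, 0.0131) and cell cycle genes (-0.36, 0.0142) were lower with Myf5Cre as lists. They had 0 called genes over all genes or adjusted over the list alone, and an adjusted p of 0.997 for each with an estimated correlation.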

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

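The tests of the tumour-cell share, of the leucocyte origin of Smarcb1 reads and of the library batch, the splits with N43L and N43R, N3 and N4, or N31 and N33 summed, and the reading of the Hox medians against 2 SE were chosen only after the results they concern had been seen. The Hox covariates and the test of shared reads were not.

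Single libraries stood apart from their group in 5 of 96 comparisons, where about 4.8 would do so by chance (1 in 20 groups). Snf5-null TATCre library N49 lay at 0.218 on the axis from Snf5-null to SS18-SSX tumours, the next library of its group at 0.084. The same library had the lowest Schwann cell list mean of its group, 2.04 log2 CPM against 2.57. Combined TATCre library 78777 had an epithelial list mean of 2.74 log2 CPM against -0.71 in the next library. Snf5-null TATCre library N43R had a T and NK cell list mean of 1.64 log2 CPM against 0.61, and combined Myf5Cre library N1 a hypoxia and glycolysis list mean of 6.54 against 5.81.

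The difference between Myf5Cre and TATCre tumours depended on the genotype for 458 genes in edgeR. The interaction was 9.7 log2 units for F2rl1, 8.66 for Meis2 and 8.11 for Fstl4, which means a larger Myf5Cre minus TATCre difference in combined tumours. It was -7.32 for Syt13, -7.26 for Reln and -7.15 for Bmp3. The call of Bmp3 ended without combined Myf5Cre library N2 (-7.28), N3 (-7) or N4 (-6.99), or Snf5-null Myf5Cre library N31 (-7.03) or N33 (-7.29). Syt13 and Reln were at -4.17 and -3.55 without combined TATCre library N49 (adjusted p = 0.131 and 0.167 in edgeR). Their calls ended as well without any of the combined Myf5Cre libraries N1 (-7.28 and -7.61), N2 (-7.23 and -7.63), N3 (-7.51 and -7.02) and N4 (-7.41 and -7.05). The same held for Snf5-null Myf5Cre libraries N30 (-7.42 and -6.66), N31 (-7.3 and -7.65) and N33 (-7.43 and -7.52), and for Snf5-null TATCre libraries N43L (-6.98 and -7.03), N43R (-7.03 and -7) and N49 (-7.2 and -7.27). Without Snf5-null TATCre library N51 Syt13 (-7, adjusted p = 0.0611) alone lost its call.

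Immune transcripts and Smarcb1 were both lower in combined than in Snf5-null tumours, although both genotypes are labelled as lacking Smarcb1. A lower share of tumour cells in Snf5-null tumours would raise all other cell types alike if their own proportions stayed the same. The tables argue against such an even shift as the whole cause. The endothelial list had a median log2 fold change of -0.23 (quartiles -0.77 and 0.51), the macrophage and myeloid list -3.9 (quartiles -4.28 and -3.6). T and NK cell (-3.96), mature skeletal muscle (-3.96) and B cell lists (-3.09) were lower too. So were the fibroblast and extracellular matrix (-1.13) and Schwann cell lists (-0.64). Red blood cell (3.15) and keratinocyte genes (0.69) went the other way, and adipocyte genes stood at 0. A larger share of some other cell types in Snf5-null tumours thus stays open. It stays open whether the remaining Smarcb1 reads of Snf5-null tumours come from leucocytes. Across 7 Snf5-null libraries, with N43L and N43R as 1, Smarcb1 and the macrophage list mean gave rho = 0.75 (exact permutation p = 0.0663, adjusted 0.0952) and Pearson r = 0.694 (exact permutation p = 0.0865, adjusted 0.0952; 0.629 without the 2 farthest), and across 8 combined libraries rho = 0.786 (0.0279, adjusted 0.0952) and r = 0.625 (0.0952, adjusted 0.0952; 0.809 without the 2 farthest).

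Against SS18-SSX tumours, 4173 genes were called the same way in combined and in Snf5-null tumours, 1930 higher and 2243 lower. These may reflect loss of Smarcb1 or the library number series, which cannot be told apart because every library without Smarcb1 has 1 series that no SS18-SSX library has. Reads shared between gene copies fit part of the pattern, as genes with over 50% of their 50-base stretches in other genes were called higher in both 6.14 times as often (22% against 3.6%, interval 5.06 to 7.4) as unique genes of like expression. For genes lower in both the ratio was 0.23, and for genes higher in combined than in Snf5-null tumours, which share a series, it was 1.38. Another 505 genes, 5.9% of the calls of combined and 5.5% of those of Snf5-null tumours, were called in opposite directions. Combined and Snf5-null libraries, all of 1 series, were exchanged within Cre labels. Of 50 splits 1 was as large, the real one, and the highest other gave 1 gene. Such an exchange makes the groups alike, so few opposite calls would follow with or without a series effect. The splits therefore do not decide whether the series had a part in these 505 calls.

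Among Snf5-null tumours, 13 Hox genes were lower with Myf5Cre than with TATCre, with a median log2 fold change of -5.76. Mature muscle or fibroblasts in the TATCre tumours, as the whole cause, needed a median above -1 with the list mean as a covariate. The median was -6.02 (quartiles -7.75 and -5.03, median SE 1.43) with muscle and -5.75 (-7.12 and -4.32, 1.39) with fibroblasts and extracellular matrix. Before, the quartiles were -8.18 and -4.93 and the SE 1.41. The tables argue against muscle as the whole cause. For fibroblasts the test does not decide, since the condition set in advance against this cause also asked for 50% of the genes still called. The calls fell to 10 of 13 with muscle and to 4 of 13 with fibroblasts, the latter short of the 50% asked for in advance, and 7 of 13 passed the unadjusted p of 0.00248 that had sufficed before, so the stricter threshold (0.000956, with 364 rather than 940 genes called) ended 3 of the 9 lost calls and a higher p of the gene itself the other 6. A part of the difference may come from fibroblasts, and the body position of the tumours, which the labels do not give, may differ between the Cre sources and was not tested.

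With every library taken as separate, other splits called fewer genes than the genotypes and Cre labels did, with 1 split as large in each case, the real one. The real and the highest other counts were 9383 and 2349 for combined against Snf5-null (50 splits), 8518 and 3439 for combined against SS18-SSX (50 splits), and 9127 and 2205 for Snf5-null against SS18-SSX tumours (50 splits). They were 940 and 746 for Cre in Snf5-null (56 splits), 344 and 106 for Cre in combined tumours (35 splits), and 458 and 193 for the interaction (50 splits). With N43L and N43R summed the genotype counts were again the largest, at 9191 and 1263 for combined and 8798 and 1833 for SS18-SSX against Snf5-null tumours (1 of 50 splits each). The same held with N3 and N4 of the combined Myf5Cre group summed (8657 and 2200 for combined against Snf5-null, 7621 and 4167 for combined against SS18-SSX) and with N31 and N33 of the Snf5-null Myf5Cre group summed (7619 and 1723 for combined, 8427 and 3792 for SS18-SSX against Snf5-null tumours; 1 of 50 splits each). For Cre in Snf5-null tumours the latter gave 124 and 61 (1 of 21 splits). With N43L and N43R summed 2 of 35 splits were as large for Cre in Snf5-null tumours (559, and 1195 with TATCre library N1 set beside the 3 Myf5Cre libraries), and for the interaction 4 of 50 (259, and up to 1483 in a split that placed N1 in the same way, which points to a structure of these samples). For the interaction 1 of 50 splits was as large with N3 and N4 summed (248, the highest other 2) and with N31 and N33 summed (79 and 23). With N3 and N4 summed, which share no tag, 3 of 35 splits were as large for Cre in combined tumours (74, and up to 185 with TATCre library 78777 set beside the Myf5Cre libraries). For the genotype comparisons no other sampled split was thus as large, with the libraries separate or 1 of these pairs summed (several pairs at once were not run). The 50 splits are a sample of those possible, and no adjustment was made over the comparisons, so chance is not excluded outright. For Cre in Snf5-null tumours and for the interaction the result rests on N43L and N43R being independent. For Cre in combined tumours it rests on N3 and N4 being so. The labels do not state either. For the SS18-SSX number series, 400 against 13, the 10 splits are too few for a share under 0.05.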

How the results depend on the processing

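The scaling by library size alone and the fits without SS18-SSX libraries N381 and A and with combined Myf5Cre libraries N3 and N4 or Snf5-null Myf5Cre libraries N31 and N33 summed were chosen only after the results had been seen. Of 253 alternative values of the main results, 198 stayed within 1.5 times the main count or on the same side of the threshold, and 55 did not. Leaving out 1 library made 156 of the 253. The balance of higher and lower calls turned in some settings, as from 58.7% to 44.7% higher in combined than in Snf5-null tumours without N31, from 46.2% to 55.7% in Snf5-null than in SS18-SSX tumours without N381 and from 31.4% to 73.9% for Cre in combined tumours fitted alone. In the first 2 of these the median log2 fold change over all genes moved too, from 0.235 to 0.101 and from -0.061 to 0.112. No named gene reversed under RLE scaling, DESeq2 or with 1 library left out. Of 154 calls of named genes 153 passed at the main settings, 152 with RLE scaling, 147 of the 148 that DESeq2 gave an adjusted p, and 143 to 151 with 1 library left out.

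For the following values the cause was not tested. With Myf5Cre libraries alone 2394 genes were higher and 3302 lower in combined than in Snf5-null tumours and 2452 higher and 3673 lower in combined than in SS18-SSX tumours, and with TATCre libraries alone 1393 were higher and 2026 lower in combined than in Snf5-null tumours. With the compared genotypes alone the Cre label gave 23 genes in combined tumours and the SS18-SSX number series 1 gene, Rprl2 (8.48 ± 0.5, adjusted p = 0.00416 in edgeR, chosen after its value was seen). With N43L and N43R summed the Cre label gave 559 genes in Snf5-null tumours and the interaction 259, and with N3 and N4 summed the Cre label gave 74 in combined tumours and the interaction 248. With N31 and N33 summed 3423 genes were higher in combined than in Snf5-null tumours, the Cre label gave 124 in Snf5-null tumours and the interaction 79. Genotype alone gave 3665 genes higher in combined than in Snf5-null tumours. DESeq2 called 2223 genes for Cre in Snf5-null and 1466 in combined tumours, 1491 for the interaction and 1350 for the SS18-SSX number series. No low-count filter gave 115 genes for that series, and library size alone 226 genes for Cre in combined tumours. Of 175 gene list tests 67 passed with the preset and 0 with an estimated correlation. The similarity of the changes was 0.607 rather than 0.672 with the Snf5-null libraries split, which removes the shared controls.

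With 1 library left out, genes higher in combined than in Snf5-null tumours numbered 3134 to 6533, Cre in Snf5-null tumours gave 122 to 1959, Cre in combined tumours 55 to 611, the interaction 60 to 1053 and the SS18-SSX number series 33 to 792. Other genotype counts stayed within 1.5 times their value. Without N381 and A, 3778 genes were higher and 3107 lower in combined than in SS18-SSX tumours, and 4929 higher and 3901 lower in Snf5-null than in SS18-SSX tumours. The position of combined tumours stayed between 0.558 and 0.598 with 1 combined library left out, and was 0.674 with Myf5Cre libraries alone. Its dependence on single Snf5-null or SS18-SSX libraries, which define the axis, was not tested. No paired analysis was run, as only a few replicate tags recur between groups. N49 names a Snf5-null and a combined TATCre library, and N1 a Snf5-null TATCre and a combined Myf5Cre library. N2 names an SS18-SSX library with no Cre stated and a combined Myf5Cre library. The labels do not say whether these libraries are related. On simulated counts 10% of interactions of 2 log2 units and 0% of 1 log2 unit were recovered, so most interactions of these sizes were not detectable with these libraries.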

Other observations

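Rps3a1 and its processed copy Rps3a3, chosen after their values were seen, took opposite levels by Cre label. Rps3a1 stood at 2.41 ± 2.56 log2 CPM in Snf5-null TATCre (n = 5), 6.5 ± 0.19 in Snf5-null Myf5Cre (n = 3), 1.78 ± 1.95 in combined TATCre (n = 4) and 7.28 ± 0.5 in combined Myf5Cre tumours (n = 4). Rps3a3 stood at 7.21 ± 0.81, -0.78 ± 0.29, 7.78 ± 1.39 and 1.01 ± 1.04 in the same groups. In SS18-SSX tumours Rps3a1 was at 3.44 ± 0.45 with Myf5Cre and 4.21 ± 0.21 with no Cre stated, and Rps3a3 at 5.58 ± 0.61 and 5.69 ± 0.52 (n = 3 each). The share of 50-base stretches that occur in other genes was 73.3% for Rps3a1 and 64.4% for Rps3a3.

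Small noncoding RNA took 13.93% of the counts of SS18-SSX library A, the shallowest library, against a mean of 4.93% ± 4.53 (SD, n = 6) in its genotype, 4.73% ± 2.23 (n = 8) in Snf5-null and 7.18% ± 2.41 (n = 8) in combined tumours. The class was a set of named genes that included Rn7sk and Rpph1. Poly(A) selection should largely leave these RNAs out, yet Rn7sk had the most counts of any gene in many libraries. Why the counts depart from the stated protocol in this way was not tested. Mitochondrial genes took 0.78% to 4.56% of the counts of a library.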
